A study of Homo sapiens with 8 samples.

How the data were processed

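Gene expression was measured in 8 peritoneal biopsies on Affymetrix PM-only arrays, which carry only perfect-match probes grouped into probe sets. Per the labels' protocols, specimens were kept in RNALater and then frozen, total RNA was extracted with Trizol, and the cDNA was fragmented and labelled with biotin using the Encore Biotin Module. The deposited values are log2 expression values, 1 column per biopsy, made by the authors with RMA (background correction, normalization between arrays and summary of the probes of a probe set), per the submitters' processing notes. The software, its version and any later step are not given in the sources used here. The log base is not stated and was taken as 2 because RMA returns log2 values and because the highest value, 13.2, would lie beyond the range of an array scanner on a natural or decimal log scale. The deposited log2 values ran from -0.51 to 13.2, were not centred, and had array medians of 1.12 to 1.29 whose quantiles were close but not identical. Scanner files were not used here.

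The table holds 54715 probe sets, of which 102 are array controls. In the platform annotation 40920 probe sets have 1 gene symbol, 864 have several and 12931 have none. Symbols were updated through the Entrez gene identifier for 40864 of the 40920 probe sets. Probe sets with several symbols or none were not tested. Y-linked genes and XIST were left out of every test and table, since the samples come from patients, which left 40855 probe sets of 19738 genes. For each gene the probe set with the highest mean over the 8 biopsies was tested. There were 10537 genes with more than 1 probe set, and for each named gene the other probe sets were compared in direction. Some opposite probe sets below the background level given next are not repeated with their genes. In EPS against the 4 other biopsies they are the only other probe set of TGFB1 and of MYC, and 1 each of COL3A1, LOXL2 and ADAM12. In EPS against PD, 1 of 4 for PTPRC was opposite. The number of arrays limits the precision of every value. As a background level, the 95th percentile of the 23 nonspecific control probe sets over all arrays was 1.38 on the log2 scale; lower values are near or within nonspecific signal.

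The labels put 4 biopsies in the EPS group, 2 in the PD group and 2 in the group of uremic controls. They do not state whether each biopsy came from a different patient, and p-values measure only the spread between these samples. Genes were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) on the log2 values, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. EPS was compared with the 4 other biopsies in a fit with 2 groups. The 3 pairwise comparisons came from 1 fit with 3 groups, which share an estimate of the spread. Log2 differences are given with limma's standard error (SE), and group means with the standard deviation (SD). A set of 33 gene lists was tested with limma's camera function with its preset correlation of 0.01 between genes, adjusted over the lists. Beside it stand camera with a correlation estimated from the data and fry, whose p tests whether the genes of a list move on balance in one direction. For each list the number of genes past the threshold is also given adjusted over the list alone.

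The groups, tests, lists, alternatives and the rule for named genes were set before the data were examined. The list tests of EPS against PD and of EPS against uremic controls were added afterwards. In EPS against the 4 other biopsies, up to 10 genes in each direction with the largest change were to be named among those past the threshold whose EPS samples did not overlap the others, filled to 5 with the lowest unadjusted p where too few passed. In each pairwise comparison 5 genes in each direction were chosen in the same way, filled to 3. From each list up to 3 genes with the lowest p were available for naming, and MSLN, KRT19, COL1A1, COL3A1, FN1, ACTA2, PDPN, VEGFA, IL6, CCL2, ADIPOQ and CD163 were named whatever their values. Immunoglobulin and T cell receptor segments, uncharacterised loci, HLA genes and genes with common inherited absence were counted and not named.

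Alternatives were a further quantile normalization, centring on array medians, the genes above the median level, the mean of all probe sets of a gene, all probe sets, a trended and robust prior, array weights, other sets of samples in the fit, a minimum change of 2-fold, the replicate number in the labels as a block, and leaving out each sample in turn. The mean level of the 18 hybridization control probe sets as a covariate, and fits without both PD or both uremic biopsies, were added after the data were seen. The scripts were tested on simulated data for 19738 genes with the real means and independent genes. The spreads were those after limma's shrinkage towards a common value, not the raw ones. At each size of change 50 genes were changed, which makes the adjustment more lenient than where few genes change. The shares below may therefore overstate what could be found in the real data. For EPS against the 4 other biopsies, 14% of genes changed 2-fold, 90% of those changed 4-fold and 96% of those changed 8-fold were recovered. For PD against uremic controls the shares were 2%, 56% and 92%. In the same simulations 8 and 7 unchanged genes were called.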

Results

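Peritoneal biopsies were profiled on arrays from 4 samples of encapsulating peritoneal sclerosis (EPS), a condition in which fibrous tissue encases the bowel, mostly after long peritoneal dialysis. They were set against 2 biopsies labelled PD and 2 labelled uremic controls. The series title names patients at first implantation of a dialysis catheter and patients having abdominal surgery for other reasons, and the labels do not say which of these the PD and uremic groups are. The comparisons ask how the EPS peritoneum differed from the others and how the PD and uremic biopsies differed from each other. The 8 arrays had medians of 1.12 to 1.29 on the log2 scale. Spiked hybridization controls, added in equal amounts by design, averaged 10.2 ± 0.66 (SD, n = 4) in EPS, 11.3 ± 0.13 (SD, n = 2) in PD and 10.5 ± 0.20 (SD, n = 2) in uremic biopsies. The interquartile range of an array was 1.86 ± 0.18 in EPS, 1.56 ± 0.03 in PD and 1.91 ± 0.09 in uremic biopsies, so that values on the PD arrays and on EPS replicate 4, at 1.61, were spread less.

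**Figure D1:**
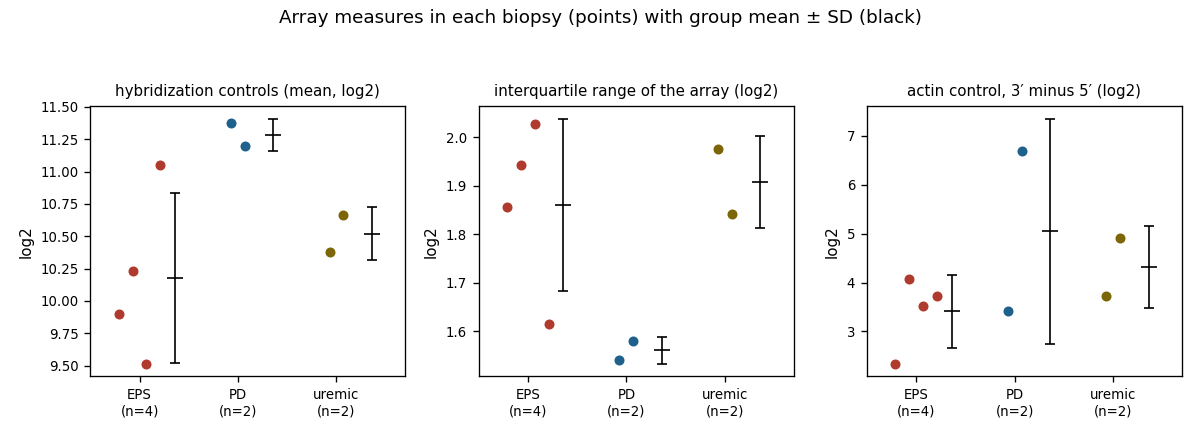
Mean log2 value of the hybridization controls, interquartile range of all log2 values and 3′ minus 5′ log2 difference of the actin control in each biopsy (points), with group mean ± SD (black). The PD arrays and EPS replicate 4 have the highest hybridization controls (11.1 to 11.4) and the smallest interquartile ranges (1.54 to 1.61), and PD replicate 2 has the largest actin difference (6.68).

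Lists of collagens, matrix glycoproteins and contractile genes were shifted upwards in EPS against the 4 other biopsies by camera with its preset correlation. None of the 3 passed with an estimated correlation (adjusted p = 0.108 for each). In the fit with 2 groups no single gene passed the threshold over all genes. Fibronectin (FN1), a matrix glycoprotein, was at 9.64 ± 0.96 (SD, n = 4) in EPS against 5.58 ± 0.48 (SD, n = 4) in the others, a log2 difference of 4.07 (SE 0.46, 16.8-fold, limma adjusted p = 0.165). Tropomyosin 2 (TPM2) differed by 1.86 (SE 0.25, adjusted p = 0.194), the chemokine receptor CXCR4 by 2.90 (SE 0.40, adjusted p = 0.194) and the junctional adhesion molecule JAML by 1.56 (SE 0.19, adjusted p = 0.165). ACTA2-AS1 differed by 2.30 (SE 0.32). It is annotated antisense to smooth muscle actin ACTA2, and its signal is uncertain for that reason. On the lower side GALNT16 differed by -1.78 (SE 0.26) with EPS at 0.92, below the background level of 1.38, AGAP11 by -1.23 (SE 0.22), GPRASP1 by -1.61 (SE 0.32) and MAP1LC3C by -1.31 (SE 0.27), and AUH was at 1.26 in EPS, below background, and 2.26 in the others. The adjusted p of these 5 genes ran from 0.204 to 0.392. In each of these 10 genes all 4 EPS biopsies lay on one side of all 4 others, which follows largely from choosing them by their p. Of all 19738 genes, 785 (3.98%) were separated in this way, where 2.86% would be expected by chance. Of 3 further TPM2 probe sets, 1 differed in the opposite direction.

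Among 33 gene lists, 13 were shifted upwards and 2 downwards in EPS against the 4 other biopsies (camera, preset correlation). With an estimated correlation 0 lists passed, the lowest adjusted p being 0.108, and 0 passed by fry. All 21 collagens had positive differences, with a median of 0.96, and 8 of them passed when adjusted over the list alone; none passed over all genes. COL3A1 differed by 2.28 (SE 0.42) and COL11A1 by 3.85 (SE 0.75), with COL11A1 at 0.35 in uremic biopsies, below background. Of 32 matrix glycoproteins, proteoglycans and crosslinking enzymes 28 were positive, with a median of 1.37, and 14 passed when adjusted over the list alone. They included the sulfatase SULF1 at 2.73 (SE 0.40) and the lysyl oxidase-like enzyme LOXL2 at 2.24 (SE 0.45). The camera adjusted p was 1.37e-12 for collagens and 4.32e-15 for matrix glycoproteins, and with an estimated correlation the adjusted p = 0.108 for both. Of 18 contractile genes 7 passed over the list alone (camera adjusted p = 1.68e-08, adjusted p = 0.108 with an estimated correlation). ACTA2, a marker shared by myofibroblasts and smooth muscle, was at 8.46 ± 0.41 (SD, n = 4) against 6.14 ± 0.68 (SD, n = 4), a difference of 2.32 (SE 0.36). Calponin CNN1 differed by 1.94 (SE 0.33).

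Matrix proteases and inhibitors had 4 of 25 genes higher over the list alone (adjusted p = 5.38e-05, and adjusted p = 0.222 with an estimated correlation), among them the inhibitor TIMP1 with a difference of 2.29 (SE 0.48), ADAM12 at 5.89 in EPS against 2.89 in the others and the fibroblast protease FAP with a difference of 2.28 (SE 0.57). Of 21 genes of TGF-beta ligands, receptors and targets 5 passed over the list alone (adjusted p = 0.000553, and adjusted p = 0.108 with an estimated correlation). They included INHBA, a subunit of activin, at 2.74 (SE 0.52) and CCN2, connective tissue growth factor, at 3.29 (SE 0.68); TGFB1 differed by 1.09 (SE 0.22) but was at 1.72 in EPS, little above background. Bone, cartilage and calcification genes (adjusted p = 0.00012, and adjusted p = 0.108 with an estimated correlation) had 1 of 17 past the list threshold, the cartilage matrix protein COMP at 3.84 (SE 0.76). COMP was at 0.40 in uremic biopsies, below background. Mesenchymal transition factors did not pass as a list (adjusted p = 0.27), and 2 of its 11 genes, SNAI2 at 1.33 (SE 0.33) and CDH2 at 1.87 (SE 0.51), passed over the list alone. CDH2 was at 0.69 in the others, below background. With the hybridization controls as a covariate the TGF-beta list did not pass.

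Immune and stress lists were also shifted in EPS against the 4 other biopsies. Macrophage and monocyte markers had 15 of 16 genes positive with a median of 1.37 (adjusted p = 5.19e-08, and adjusted p = 0.311 with an estimated correlation), led by the scavenger receptor MSR1 at 2.58 (SE 0.45), the 1 gene that passed over the list alone. Without both PD biopsies this list did not pass (adjusted p = 0.0501). Neutrophil markers (adjusted p = 0.00012, and adjusted p = 0.31 with an estimated correlation) had no gene past the list threshold, and S100A8 differed by 3.20 (SE 1.02). With the replicate number as a block the neutrophil list did not pass. Inflammatory cytokines and chemokines (adjusted p = 0.000328, and adjusted p = 0.299 with an estimated correlation) had 1 of 26 past it, the adhesion molecule ICAM1 at 1.99 (SE 0.45); CCL2 differed by 2.04 (SE 0.68) and IL6 by 2.78 (SE 0.93). The mean of the cytokine list was 3.35 and 3.52 in EPS replicates 1 and 3, 2.41 and 2.44 in EPS replicates 2 and 4, and 2.03 to 2.35 in the 4 others. IL6 was at 0.89 in EPS replicate 2 and averaged 0.77 in the 4 others, both below background. The neutrophil list mean in EPS replicate 2, at 1.35, lay within the range of the 4 others, 1.13 to 1.66. Immediate early genes, which respond within minutes to stimulation or handling, had 19 of 19 positive and a median of 2.05 (adjusted p = 7.66e-10, and adjusted p = 0.312 with an estimated correlation), with 2 past the list threshold. CCN1 differed by 4.70 (SE 1.05), MYC by 2.08 (SE 0.51). The list mean was 6.96 in EPS replicate 1, 7.69 in EPS replicate 3 and 5.84 in PD replicate 1, against 3.24 to 4.57 in the other 5 biopsies. Heat shock and protein folding (adjusted p = 0.000911, and adjusted p = 0.312 with an estimated correlation), complement and coagulation (adjusted p = 0.0239, and adjusted p = 0.553 with an estimated correlation) and hypoxia and glycolysis (adjusted p = 0.0271, and adjusted p = 0.533 with an estimated correlation) were shifted upwards, with the chaperone HSPA5 at 1.75 (SE 0.51), complement C2 at 1.62 (SE 0.30) and P4HA1, an enzyme of collagen hydroxylation whose other probe set differed in the opposite direction, at 1.83 (SE 0.62). Without both PD biopsies the heat shock, complement and hypoxia lists did not pass. With the level of the hybridization controls as a covariate, these 3 lists and the macrophage and cytokine lists did not pass. The complement list did not pass without EPS replicate 2, EPS replicate 3 or PD replicate 1, nor the hypoxia list without EPS replicate 1 or 3 or either PD biopsy.

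The lists shifted downwards were adipocyte markers (adjusted p = 8.08e-07, and adjusted p = 0.483 with an estimated correlation) and mesothelial markers (adjusted p = 0.025, and adjusted p = 0.596 with an estimated correlation). The adipocyte list mean was 2.53 ± 0.57 (SD, n = 4) in EPS, 2.19 ± 0.10 (SD, n = 2) in PD and 6.60 ± 0.88 (SD, n = 2) in uremic biopsies, and ADIPOQ, the fat cell hormone adiponectin, differed by -3.16 (SE 1.54). The mesothelial markers are genes of the cell layer that lines the peritoneum. Their list mean was 1.59 in EPS and 2.21 in the others, near the background level of 1.38, and their median difference was -0.24. Among them 1 gene, ITLN1, passed over the list alone. It was at 0.72 ± 0.23 (SD, n = 4) in EPS, below background, and 6.44 ± 3.12 (SD, n = 4) in the others. MSLN, the classical mesothelial antigen, differed by -0.20 (SE 0.22) and KRT19 by -0.01 (SE 0.38), a sign that turned with a further quantile normalization and with centred medians. The mesothelial list did not pass without EPS replicate 1, 2 or 3 or PD replicate 2, with a further quantile normalization or with the hybridization covariate, and the adipocyte list did not pass without both uremic biopsies. The direction of these lists, and of the hypoxia list, turned under 1 of 20 alternatives each. COL1A1 differed by 1.60 (SE 0.73), PDPN by 2.38 (SE 0.54), VEGFA by 1.29 (SE 0.98) and CD163 by 2.28 (SE 1.05), none past the threshold. Other probe sets differed in the opposite direction for COL1A1 (1 of 4) and VEGFA (1 of 3). T cell markers came nearest to the threshold among the other lists (adjusted p = 0.059).

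**Figure D2:**
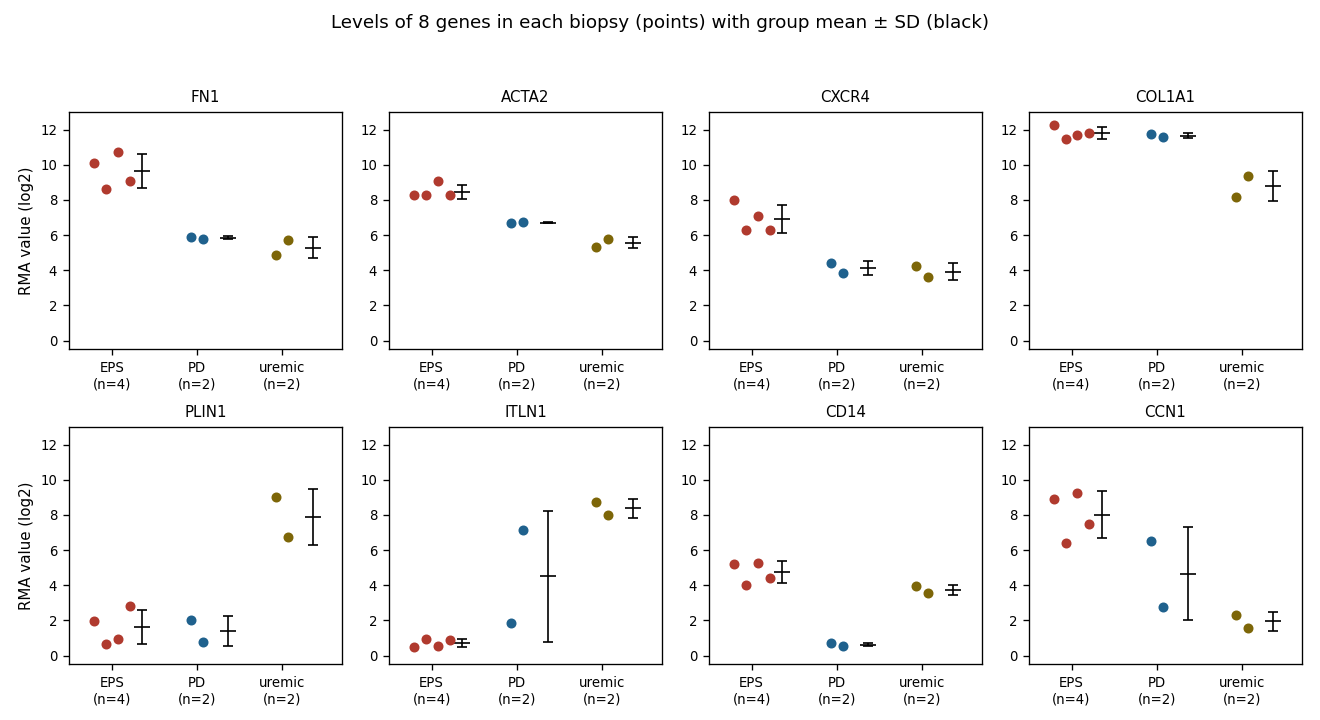
RMA log2 values of 8 genes in each biopsy (points), with group mean ± SD (black), in EPS (n = 4), PD (n = 2) and uremic biopsies (n = 2). FN1, ACTA2 and CXCR4 lie higher in all 4 EPS biopsies than in the 4 others, COL1A1 is at 11.8 in EPS and 11.6 in PD, and CD14 is lowest in PD.

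In EPS against the 4 other biopsies, limma called 0 of 19738 genes, the lowest adjusted p was 0.165, and 1316 genes had an unadjusted p under 0.05 where 987 would be expected by chance. The fit with 3 groups called 18 genes. It leaves the differences unchanged but takes the gap between PD and uremic biopsies out of the spread. COL1A1, at 11.65 in PD and 8.78 in uremic biopsies, has such a gap. Array weights gave 9 genes and leaving out PD replicate 1 gave 12. Leaving out both PD biopsies gave 71, of which 49 were lower, but that fit compares EPS with the uremic biopsies alone.

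Against the PD biopsies alone, macrophage and monocyte markers were shifted upwards in EPS (camera adjusted p = 5.55e-14, and adjusted p = 0.28 with an estimated correlation). Neutrophil markers were shifted upwards too (adjusted p = 0.0291, and adjusted p = 0.478 with an estimated correlation), a call kept under 10 of 18 alternatives. T cell markers (adjusted p = 0.111) and B and plasma cell markers (adjusted p = 0.624) did not pass. Their list means were near background, at 1.445 and 1.685 in EPS and 1.133 and 1.633 in PD, which limits what these tests can show. CD14, the endotoxin co-receptor of monocytes, was at 4.74 ± 0.62 (SD, n = 4) in EPS and at 0.62 ± 0.10 (SD, n = 2) in PD, below background, a difference of 4.12 (SE 0.39, 17.4-fold, adjusted p = 0.0233). The leukocyte phosphatase PTPRC (CD45) was higher than in PD by 4.21 (SE 0.41, adjusted p = 0.0233) and LAPTM5 by 3.77 (SE 0.40, adjusted p = 0.0341). Lysozyme LYZ was higher by 4.06 (SE 0.52, adjusted p = 0.0481) and the Fc receptor FCGR2A by 4.47 (SE 0.58, adjusted p = 0.0481). In uremic biopsies CD14, PTPRC, LAPTM5, LYZ and FCGR2A were at 3.7, 4.3, 4.8, 5.6 and 6.3. Their PD means were 0.6 to 2.6, so PD was the low group. In total 15 genes were higher and 3 lower, of which 4 belong to families not named here. LRRC38 was lower, with a difference of -2.12 (SE 0.26, adjusted p = 0.0481), with EPS below background. NPBWR1 and HOPX did not pass, at -1.65 (SE 0.22) and -1.47 (SE 0.23), and 1 of 2 other HOPX probe sets differed in the opposite direction.

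Macrophage and monocyte markers were the most strongly shifted list in EPS against PD, with 16 of 16 genes positive, a median of 2.54 and 12 genes past the threshold over the list alone, 2 of them over all genes (fry adjusted p = 0.0212). AIF1 was higher by 2.39 (SE 0.30, adjusted p = 0.0481), at 6.46 in EPS, 4.07 in PD and 5.86 in uremic biopsies. Values on the PD arrays were spread less and their hybridization controls were higher, as given above. Matrix glycoproteins had a median of 1.07 and 10 of 32 genes past the threshold over the list alone (adjusted p = 3.61e-08, and adjusted p = 0.307 with an estimated correlation). Collagens (5 of 21, adjusted p = 0.00114, and adjusted p = 0.307 with an estimated correlation) and contractile genes (6 of 18, adjusted p = 0.00114, and adjusted p = 0.307 with an estimated correlation) were shifted upwards as well. Among all genes above the median level the median difference of EPS against PD was 0.21, and tested among these genes alone collagens and contractile genes did not pass, nor collagens with the hybridization covariate. FN1 differed by 3.78 (SE 0.57, adjusted p = 0.0669), with 1 of 6 other probe sets in the opposite direction, ACTA2 by 1.75 (SE 0.31, adjusted p = 0.11) and LOXL2 by 2.74 (SE 0.49, adjusted p = 0.11). COL1A1, the main fibrillar collagen, differed by 0.17 (SE 0.37, adjusted p = 0.887). In all 19 lists were called, 17 upwards and 2 downwards, and none with an estimated correlation.

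The count of 18 genes fell to 1 without EPS replicate 1, 3 without EPS replicate 2, 5 without EPS replicate 3, 1 without PD replicate 1 and 0 without either uremic biopsy, which enter only through the spread. It was 0 with only the 6 EPS and PD samples in the fit, and without PD replicate 1 collagens, contractile genes and matrix glycoproteins did not pass (adjusted p = 0.0662 each), while macrophage markers did (adjusted p = 4.02e-09).

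Against the uremic biopsies, collagens were shifted upwards and adipocyte markers downwards in EPS. Neither list passed with an estimated correlation (adjusted p = 0.0612 each). COL1A1 was at 11.8 ± 0.34 (SD, n = 4) in EPS and 8.78 ± 0.85 (SD, n = 2) in uremic biopsies, a rise of 3.04 (SE 0.37, adjusted p = 0.0194). COL1A2 rose by 3.78 (SE 0.43, adjusted p = 0.0134), COL3A1 by 2.98 (SE 0.34, adjusted p = 0.0134), FN1 by 4.35 (SE 0.57, adjusted p = 0.0235) and the proteoglycan BGN by 3.87 (SE 0.47, adjusted p = 0.0194). The largest rises among genes past the threshold were COMP at 4.98 (SE 0.69) and CTHRC1, secreted by activated fibroblasts, at 4.52 (SE 0.72). COMP was at 0.40 in uremic biopsies, below background, so its fold and rank are uncertain. ACTA2 rose by 2.89 (SE 0.31), TPM2 by 2.07 (SE 0.29, 1 of 3 other probe sets opposite) and FAP by 3.38 (SE 0.31, adjusted p = 0.00861). In total 21 genes were higher and 56 lower.

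The lower genes were led by ITLN1 at -7.66 (SE 1.15, adjusted p = 0.0432), with EPS at 0.72, below background, and by genes of fat storage. Perilipin PLIN1, which coats lipid droplets, differed by -6.28 (SE 0.77), SCD, which makes monounsaturated fatty acids, by -5.59 (SE 0.30, adjusted p = 0.000934), PLIN4 by -5.55 (SE 0.38) and GPAM, of triglyceride synthesis, by -5.55 (SE 0.41). PLIN4 was at 0.94 in EPS, below background. All 20 adipocyte markers were lower in EPS, with a median of -4.50, 18 past the threshold over the list alone and 14 over all genes (camera adjusted p = 6.54e-42, and adjusted p = 0.0612 with an estimated correlation, fry adjusted p = 0.00908). Collagens had 12 of 21 genes past the threshold over the list alone and 4 over all genes (adjusted p = 1.18e-20, and adjusted p = 0.0612 with an estimated correlation, fry adjusted p = 0.0117). Matrix glycoproteins (14 higher and 2 lower of 32, adjusted p = 1.12e-13, and adjusted p = 0.163 with an estimated correlation, fry adjusted p = 0.124) and contractile genes (7 of 18, adjusted p = 7.7e-10, and adjusted p = 0.0651 with an estimated correlation) were shifted upwards. The oxidative stress list was shifted downwards (adjusted p = 0.00752, and adjusted p = 0.163 with an estimated correlation), with NQO1, a quinone reductase, differing by -3.29 (SE 0.41, adjusted p = 0.0194). NQO1 was at 1.73 in EPS, 2.17 in PD and 5.02 in uremic biopsies, and the oxidative stress list was lower in PD than in uremic biopsies too. This list did not pass without uremic replicate 1. Immediate early genes (adjusted p = 1.9e-12, and adjusted p = 0.267 with an estimated correlation) were shifted upwards with 19 of 19 positive, and interferon response genes downwards (adjusted p = 0.00135, and adjusted p = 0.521 with an estimated correlation), the latter not without uremic replicate 2. Macrophage markers did not pass (adjusted p = 0.0551, median 0.29).

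The count of 77 genes fell to 9 without EPS replicate 1, 42 without EPS replicate 2, 29 without EPS replicate 3, 37 without EPS replicate 4 and 5 without uremic replicate 1, all of these 5 being lower genes. Without uremic replicate 2 it was 70, with 7 genes higher instead of 21. Of the 16 lists called, none passed with an estimated correlation.

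**Figure D3:**
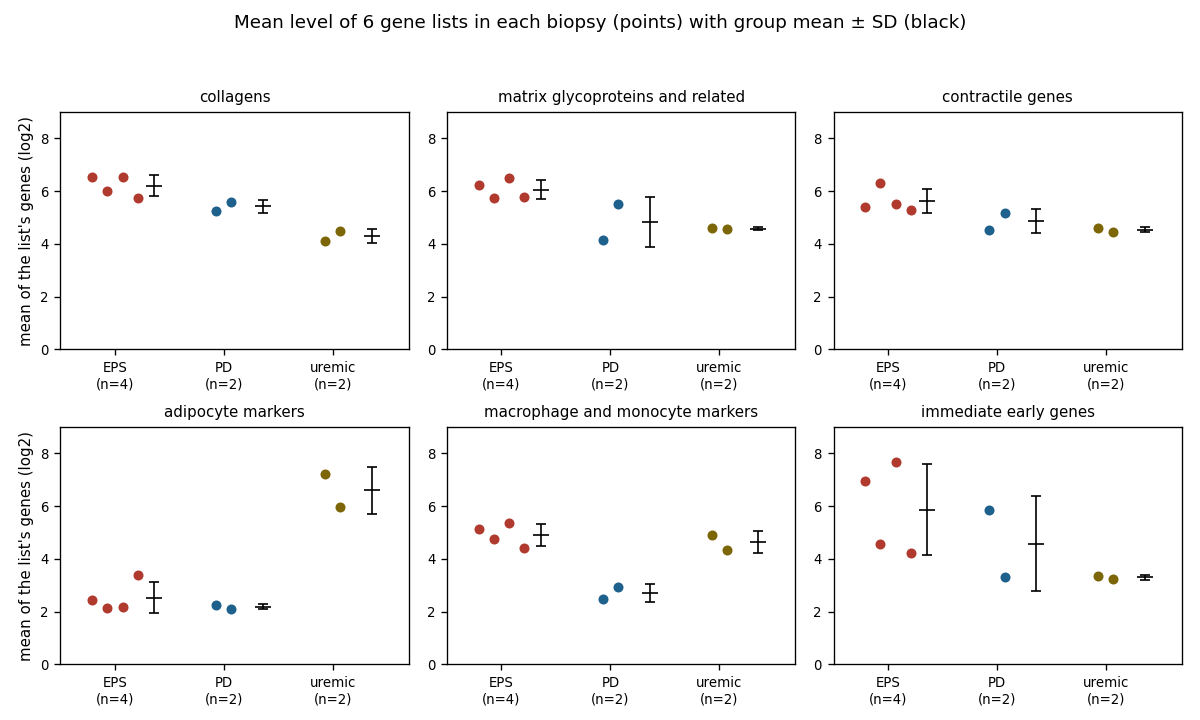
Mean log2 level of the genes of 6 lists in each biopsy (points), with group mean ± SD (black), in EPS (n = 4), PD (n = 2) and uremic biopsies (n = 2). Adipocyte markers stand at 5.98 and 7.23 in the uremic biopsies and at 2.12 to 3.37 elsewhere, and macrophage markers at 2.47 and 2.95 in PD and at 4.33 to 5.36 elsewhere.

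In PD against the uremic biopsies, adipocyte markers and macrophage markers were shifted downwards. Neither list passed with an estimated correlation (adjusted p = 0.16 and adjusted p = 0.192), and no macrophage marker passed over all genes. SCD was at 1.58 ± 0.59 (SD, n = 2) in PD and 9.36 ± 0.14 (SD, n = 2) in uremic biopsies, a difference of -7.77 (SE 0.35, adjusted p = 0.000203). Lipoprotein lipase LPL differed by -7.39 (SE 0.86, adjusted p = 0.0379), leptin LEP by -6.88 (SE 0.72, adjusted p = 0.026), CES1 by -6.22 (SE 0.52, adjusted p = 0.00724) and MGST1 by -5.73 (SE 0.40, adjusted p = 0.00331). CES1 was at 0.71 in PD, below background. The glutathione peroxidase GPX1 was also lower, with a difference of -3.51 (SE 0.41, adjusted p = 0.0379). In total 21 genes were lower and 0 higher in limma's test, with 1615 genes lower and 914 higher at an unadjusted p under 0.05. Under some alternatives genes were called higher, up to 9 with the trended robust prior. Nearest to the threshold on the higher side were LRRC38 at 2.08 (SE 0.30), COL1A1 at 2.87 (SE 0.43, adjusted p = 0.062) and FAP at 2.20 (SE 0.36).

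Adipocyte markers were lower in PD in 20 of 20 genes, 18 past the threshold over the list alone (camera adjusted p = 3.33e-27, and adjusted p = 0.16 with an estimated correlation, fry adjusted p = 0.0111). Macrophage and monocyte markers were lower in 16 of 16, with a median of -2.20 and 10 past the list threshold (adjusted p = 5.88e-10, and adjusted p = 0.192 with an estimated correlation, fry adjusted p = 0.0283); CD14 differed by -3.11 (SE 0.45) and TYROBP, an adaptor of myeloid receptors, by -2.69 (SE 0.53). Collagens were shifted upwards, 6 of 21 past the list threshold (adjusted p = 1.83e-05, and adjusted p = 0.249 with an estimated correlation). Oxidative phosphorylation (5 of 17 lower over the list alone, adjusted p = 1.52e-07, and adjusted p = 0.249 with an estimated correlation) and ribosomal proteins (none past the list threshold, adjusted p = 1.95e-05, and adjusted p = 0.498 with an estimated correlation) were shifted downwards. Among all genes above the median level, the median difference of PD against uremic biopsies was -0.31 on the log2 scale, and with a further quantile normalization the ribosomal list did not pass. The remaining calls were oxidative stress, blood endothelial, interferon, hypoxia, complement and heat shock lists downwards and immediate early, cell cycle and intestinal epithelium lists upwards, with adjusted p from 7.23e-05 to 0.0343, and adjusted p from 0.16 to 0.756 with an estimated correlation. The intestinal epithelium list mean was 1.25 in PD and 0.88 in uremic biopsies, both below background. The nonspecific control probe sets averaged 0.74 on the PD arrays and 0.27 on the uremic arrays. Without PD replicate 1 the number of lists called fell from 14 to 7.

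The count of 21 genes was 0 with only the 4 PD and uremic samples in the fit. It was 5, 12 and 7 without EPS replicates 1, 2 and 3, 6 without PD replicate 1, 90 without PD replicate 2, 2 without uremic replicate 1 and 45 without uremic replicate 2, where a lone sample is assumed to vary like the other groups.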

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

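All tests in this part except the search for outlying samples were chosen after the results were seen. In the EPS group of 4, values of 124 measures were searched for a sample far from the other 3, and 2 were found; chance alone would give about 1 in 20. ACTA2 was at 9.07 in EPS replicate 3 and between 8.25 and 8.26 in the other 3 EPS biopsies. The mean of the water and solute transport list was 1.90 in EPS replicate 2 and between 1.71 and 1.74 in the others.

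The count of genes changed in EPS against the 4 other biopsies was 0, a value that all 35 splits of the 8 samples into 4 and 4 must reach, so these splits say nothing about chance for that count. The highest count in another split was 1. One of the splits with 1 gene set the 4 arrays with the highest hybridization controls against the rest. For the gene lists, 3 of the 35 splits, the real one included, gave at least 15 lists, and the highest other count was 16, so chance is not excluded for that count. The split by hybridization controls gave 14 lists. At an unadjusted p under 0.05 the real split gave 1316 genes and 9 of the 35 splits gave as many, up to 2760, which points to structure among the samples other than EPS.

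The mean of 53 collagen and matrix genes was 6.12 ± 0.37 (SD) in EPS, 5.06 ± 0.68 in PD and 4.47 ± 0.08 in uremic biopsies. Weaker sample signal on the PD arrays, as the whole cause, was argued against by the difference from uremic biopsies, which does not use the PD arrays. The median difference of 1.37 lay at percentile 100 of 10000 random lists of the same size and mean level, whose middle range was -0.29 to 0.03. Such lists drew genes independently, whereas these genes move together (estimated correlation 0.152 for collagens and 0.289 for matrix glycoproteins). The range of such lists is therefore too narrow, and the percentile is no measure of chance. Fat in the uremic biopsies, which dilutes other tissue, could be the whole cause only if EPS did not exceed PD, where fat cell genes are low too. All 4 EPS biopsies lay above both PD biopsies and the fry p for EPS against PD was 0.0335, and 0.0129 without PD replicate 2, but it was 0.259 without PD replicate 1, so fat as the whole cause stays open, as does the disease itself, which was not tested. Weak PD signal added to fat stays open too: the median of 1.07 in EPS against PD lay at percentile 100 of matched random lists with a middle range of 0.09 to 0.53, but these were not drawn without PD replicate 1.

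Macrophage and monocyte markers were low in both PD biopsies, with list means of 2.47 and 2.95 against 4.33 to 5.36 in the 6 others. Weaker signal on the PD arrays would lower genes of similar brightness alike. The median of 2.54 in EPS against PD lay at percentile 100 of 10000 matched random lists, whose middle range was -0.05 to 0.78. Those lists drew genes independently, whereas the markers move together (estimated correlation 0.209), so the range is too narrow. Brightness was matched on the mean of all 8 arrays, low PD values included. The list was also picked for its shift. These values show only that it differed by more than genes of similar mean level, and weak PD signal is not excluded. More degraded RNA in the PD biopsies cannot be told apart from a lower macrophage content: only 1 of the 2 PD samples, PD replicate 2, had 3′ minus 5′ differences of actin and GAPDH above all 6 others. PD replicate 1 lay inside their range in both and had the lowest list mean, but 1 sample excludes nothing. Fewer macrophages in the PD specimens may account for the pattern and were not tested otherwise.

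Smooth muscle of bowel or vessel wall in the EPS specimens might raise contractile genes. Cells of this kind would bring all their transcripts. In EPS against the 4 other biopsies 11 genes most typical of smooth muscle had a median difference of 0.418 (SD 0.75). The 7 genes shared with myofibroblasts had 1.86. This gap cannot decide, because these 7 are the contractile genes that passed over the list alone. The sets also differ in brightness. In EPS several of the 11 were dim, such as CASQ2 at 1.95 and SMTN at 2.20, where TPM2 was at 10.3 and CALD1 at 10.5. MYH11 differed by 0.68 (SE 0.94) and SYNPO2 by -0.66 (SE 0.30), while ACTG2, at 2.04 (SE 0.87), went with this explanation. MYH11 was highest in EPS replicate 2, at 9.27, and PD replicate 2, at 8.85, and MYH11, MYLK and ACTG2 were each lowest in a uremic biopsy, at 5.56, 5.80 and 0.85. Whether myofibroblasts or smooth muscle account for the higher ACTA2 and CNN1 is left open.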

How the results depend on the processing

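The covariate of hybridization controls and the fits without both PD or both uremic biopsies were chosen after the data were seen, as were the list results for EPS against PD and EPS against uremic biopsies. For 117 pairs of a gene and a comparison, 2132 of 2140 values under the alternatives had the direction of the reported one. Much of this was fixed in advance. Several alternatives cannot change a difference, such as another prior, the 2-fold minimum, or leaving out samples of a group not compared. Many of the genes were also named for a low p in the same data. The exception was KRT19 in EPS against the 4 other biopsies, whose difference turned from -0.0085 to 0.037 with a further quantile normalization, 0.021 with centred medians, 0.27 with the hybridization covariate and 0.36 without both uremic biopsies, and ranged from -0.32 to 0.22 when single samples were left out. The cause was not tested for any of the moves below, except where fewer samples in the fit make it.

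Genes in EPS against the 4 other biopsies (0) became 9 with array weights and 18 with 3 groups in the fit, where the differences are the same. They ranged from 0 to 12 with single samples left out. Without both PD biopsies there were 71, but that fit compares EPS with the uremic biopsies alone. Genes in EPS against PD (18) became 10 with centred medians, 31 with the mean of all probe sets, 9 with all probe sets tested, 1 with array weights, and 0 with only the 6 samples or with the hybridization covariate, with a range of 0 to 22 when single samples were left out. Genes in EPS against uremic biopsies (77) became 121 with array weights and 20 with the hybridization covariate, with a range of 5 to 71. Without uremic replicate 2 there were 70, and the higher genes among them fell from 21 to 7. Genes in PD against uremic biopsies (21) became 44 among genes above the median level, 57 with the mean of all probe sets, 48 with the trended robust prior, 5 with array weights, 0 with only the 4 samples and 4 with the hybridization covariate, with a range of 2 to 90. None of the 21 was higher, but 9 were with the trended robust prior, 6 with the mean of all probe sets, 7 without PD replicate 2, and 1 at most under each other alternative.

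With an estimated correlation 0 lists passed in each of the 4 comparisons, against 15, 19, 16 and 14. Lists in EPS against the 4 other biopsies ranged from 13 to 17 when single samples were left out, and 12 of the 15 passed in the same direction without any single sample. In the other comparisons fewer lists were this stable: 2 of 19 in EPS against PD, 11 of 16 in EPS against uremic biopsies and 6 of 14 in PD against uremic biopsies. Some of those fits leave a lone sample in a group. With the hybridization covariate 12 lists passed, 8 upwards and 4 downwards, and 8 of them were among the 15 in the same direction. The TGF-beta, mesothelial, macrophage, complement, cytokine, hypoxia and heat shock lists did not pass with it. Lists in EPS against PD (17 upwards, 2 downwards) became 12, all upwards, with a further quantile normalization, 6 among genes above the median level and 5 with the hybridization covariate, with a range of 5 to 18. Lists in EPS against uremic biopsies ranged from 13 to 17. Lists in PD against uremic biopsies (14) became 8 with a further quantile normalization, with a range of 7 to 15.

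With the replicate block, the genes called were 0 in EPS against the 4 other biopsies, 0 in EPS against PD, 12 in EPS against uremic biopsies and 10 in PD against uremic biopsies, and the lists 13, 18, 15 and 14. All 12 and all 10 were lower genes, where the main fit had 21 higher and 56 lower, and 0 higher and 21 lower. The labels do not say whether a shared replicate number marks anything beyond a number. Across genes, which are not independent replicates, the deviations of same-numbered samples from their group means correlated at 0.249 and 0.364 between EPS and PD, 0.048 and 0.033 between EPS and uremic, and -0.00032 between PD and uremic biopsies. With 2 shared numbers these values were too few to take the samples as paired or to exclude it. Genes below 1.38 on the log2 scale have signal near background on these arrays, which limits what can be said of their folds.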

Other observations

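The list tests of EPS against PD and of EPS against uremic biopsies in this part were added after the data were seen, and the others were planned. Angiogenesis factors and receptors did not pass as a list in EPS against the 4 other biopsies (camera adjusted p = 0.225), though HIF1A, the hypoxia-inducible transcription factor, differed by 1.86 (SE 0.39) and was the 1 of 16 genes past the threshold over the list alone. Against PD it was shifted upwards (adjusted p = 0.0434, and adjusted p = 0.307 with an estimated correlation, fry adjusted p = 0.0404), a call kept under 4 of 18 alternatives, and against uremic biopsies it did not pass (adjusted p = 0.994). Blood endothelial markers did not pass in EPS against the 4 other biopsies (median -0.07, adjusted p = 0.844), with ENG at 1.03 (SE 0.41), and this value averages groups that lay on either side of EPS. Against PD 12 of 15 were positive (median 0.13, adjusted p = 0.0826). Against uremic biopsies 12 of 15 were negative (median -0.47, adjusted p = 0.0139, and adjusted p = 0.521 with an estimated correlation), and this list did not pass without EPS replicate 3, EPS replicate 4 or uremic replicate 2. Interferon response genes had 13 of 17 negative differences in EPS against the 4 other biopsies (median -0.35, adjusted p = 0.225), with IFIT3 at -1.22 (SE 0.48). In EPS against the 4 other biopsies, cell cycle genes (adjusted p = 0.569), T cell markers (adjusted p = 0.059) and B and plasma cell markers (adjusted p = 0.509) did not pass. The T cell and B cell list means were near background. Against uremic biopsies cell cycle genes were shifted upwards, with 17 of 22 positive (adjusted p = 0.0237, and adjusted p = 0.251 with an estimated correlation), but not without EPS replicate 4 or either uremic biopsy. Nor did this list pass among genes above the median level, with the mean of all probe sets or with the replicate block. Its mean was 1.61 in EPS and 1.41 in uremic biopsies, close to background.

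CALB2 (calretinin), another mesothelial marker, was at 0.65 in EPS, below background, 1.52 in PD and 3.96 in uremic biopsies. ITLN1 was at 7.15 in PD replicate 2 and 1.87 in PD replicate 1, and at 0.49 to 0.95 in the 4 EPS biopsies. CFD, made by fat cells, was at 7.38 in uremic biopsies, 2.94 in PD and 3.22 in EPS.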
